A study of Mus musculus with 16 samples.

How the data were processed

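The deposited files hold whole-number read counts per Entrez gene, 1 file for each of 16 RNA-seq libraries, with gene lengths that are the same in all files, per the file headers. Per the labels' protocols, FACS-sorted AML246 cells gave total RNA through a column kit and libraries were sequenced on an Illumina NextSeq500. Per the submitters' processing notes, featureCounts, edgeR and limma were used with the mm10 genome, without versions or roles. The aligner is not given in the sources used here. Every listed gene exceeds 0.5 CPM in at least 3 libraries, so low genes were left out before deposit. Entrez numbers were matched to symbols in a GRCm38 gene table, which named 13216 of 13652 genes.

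The libraries were placed in 8 groups of 2 replicates by their titles. The labels do not say whether replicates A and B are separate cultures, so the p-values measure a spread that may be technical. No replicate term was used in the main fit, since the labels do not pair the replicate letters between groups. The difference of A and B correlated by over 0.1 across genes between 8 of 28 pairs of groups, so a fit with a replicate block was an alternative. Total counts ran from 12962801 to 26509803 per library. Counting intervals and floors cover counting error only.

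Counts were normalised with TMM and tested in 1 fit of all 16 libraries with 1 mean per group, by the quasi-likelihood F test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with robust dispersions. The fit had 8 residual degrees of freedom and a common biological coefficient of variation of 10.9%. The planned filter on low counts (filterByExpr) removed 0 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, two-sided. There were 10 comparisons, of which 4 were main: day 12 against day 0, Cd11b-high against total cells at day 12, and 12 days off against day 12 and against day 0. The standard error of a log2 fold is its size over the square root of F. CPM values use TMM-scaled library sizes.

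Named genes followed a rule fixed, with the lists, comparisons and alternative settings, before the data were examined. Spi1 and Itgam were named in every comparison. Each main comparison named the 6 largest rises and the 6 largest falls among called genes with a mean of at least 10 CPM, a symbol that is not a predicted gene, and libraries of the groups that did not overlap. It also named up to 3 members of each list with the lowest adjusted p. A gene named in 1 comparison may be given in another, and some genes that fit the rule are not reported here. A gene with 1 to 3 reads in a group is given with an exact 95% counting interval, and a gene with 0 reads against a floor of 3 reads over the group.

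The 25 gene lists, written from textbook knowledge, covered macrophage and monocyte, neutrophil, azurophil granule, stem and progenitor, PU.1 target, lysosomal, Fc receptor and ITAM, complement, MHC class II, interferon-stimulated, mitosis, DNA replication, ribosome biogenesis, cholesterol synthesis, p53 target, cytokine and chemokine, haematopoietic transcription factor, immediate-early and heat-shock, basophil and mast cell, eosinophil, erythroid, megakaryocyte and platelet, B cell, T and NK cell, and dendritic cell genes. They had 5 to 40 members in the files, and some genes stand in more than 1 list. The lists of other lineages also served as markers of cells that the culture or the gate could hold. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 25 lists within a comparison, and again with an estimated correlation.

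Overlaps between comparisons were set against the overlap of independent lists and against 20 simulations of unchanged groups. The alternatives were RLE size factors, library size alone, no filter, DESeq2 1.42.0, limma-voom, a fit of the 4 libraries compared, a replicate block, and leaving out each library of the groups compared. For lists the alternatives were an estimated correlation, fry, RLE factors, the block and leaving out libraries. A filter at a mean of 1 CPM, a fit without 15 mitochondrial genes, 2 list tests without the gene of the sort marker, 3 further lists and a day 12 against day 4 comparison were added after seeing the data.

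The edgeR script was tested on simulated counts of 13652 genes, with the sizes of all 16 libraries and each gene's mean over them. Changes were set in the day 12 libraries, only in genes with a mean of at least 1 CPM. In day 12 against day 0, the script recovered 43.3% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 97.0% of those changed 4-fold. There were 5 false calls among 157. A simulated list of 30 genes raised 1.5-fold gave a camera p of 7.2e-35, and 0 of 100 random lists had a p under 0.05. The simulated genes varied independently of each other, so the preset correlation was not put to the test.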

Results

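RNA sequencing counted transcripts in AML246 cells, a mouse acute myeloid leukaemia line grown with interleukin-3, over a course of 24 days. Doxycycline at 0.1 µg/mL was given from day 0 to day 12 and then removed. The series title ties this schedule to the restoration and later knockdown of PU.1, the myeloid transcription factor encoded by Spi1. The 16 libraries fell into 8 groups of 2. These were untreated cells at day 0, cells after 4, 8 and 12 days of doxycycline, Cd11b-high cells sorted at day 12, and cells 4, 8 and 12 days after withdrawal (course days 16, 20 and 24). Apart from the Cd11b-high sort, all libraries came from total viable cells. Total counts per library ranged from 12962801 to 26509803 over 13652 genes. Gene levels are normalised CPM, as mean ± SD of n = 2 libraries. Log2 folds carry the standard error (SE) of the edgeR fit over all 16 libraries.

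Spi1 followed the doxycycline schedule. Spi1 (Entrez 20375, chromosome 2, 91082374 to 91115759, GRCm38) stood at 61.5 ± 6.69 CPM at day 0 and at 239 ± 13.8, 197 ± 15.2 and 222 ± 4.72 CPM after 4, 8 and 12 days of doxycycline. It returned to 60.8 ± 5.91 CPM 4 days after withdrawal and stood at 46.5 ± 2.35 and 46.0 ± 12.5 CPM after 8 and 12 days. At day 12 it was 3.61-fold above day 0 (log2 fold 1.85, SE 0.15, edgeR adjusted p = 1e-07). Against day 0, its log2 fold was -0.02 after 4 days off, -0.41 after 8 (edgeR adjusted p = 0.051) and -0.42 after 12 (edgeR adjusted p = 0.035). The call after 12 days off was lost with RLE factors (adjusted p = 0.063), with DESeq2 (0.054), with the 4 libraries alone (0.26), without day 0 replicate A (0.23) and without replicate B of that time (log2 fold -0.09, 0.54). Without replicate A of that time the log2 fold was -0.73. After 8 days off, an adjusted p under 0.05 was reached with library size alone (0.045), with the 4 libraries alone (0.0033) and with a replicate block (0.041).

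Itgam, which encodes Cd11b, an integrin chain of mature myeloid cells and the marker of the sort, moved over a far wider range. Itgam (Entrez 16409, chromosome 7, 128062640 to 128118491, GRCm38) stood at 1.59 ± 0.252 CPM at day 0. It reached 559 ± 92.4, 571 ± 14.8 and 694 ± 35.3 CPM after 4, 8 and 12 days of doxycycline. After withdrawal it fell to 69.7 ± 18, then 4.79 ± 0.783, then 1.29 ± 0.301 CPM at 4, 8 and 12 days. At day 4 it was 354-fold above day 0 (log2 fold 8.47, SE 0.25, edgeR adjusted p = 3.6e-12). After 12 days off it did not differ by the test from day 0 (log2 fold -0.27, SE 0.34, edgeR adjusted p = 0.54).

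**Figure D1:**
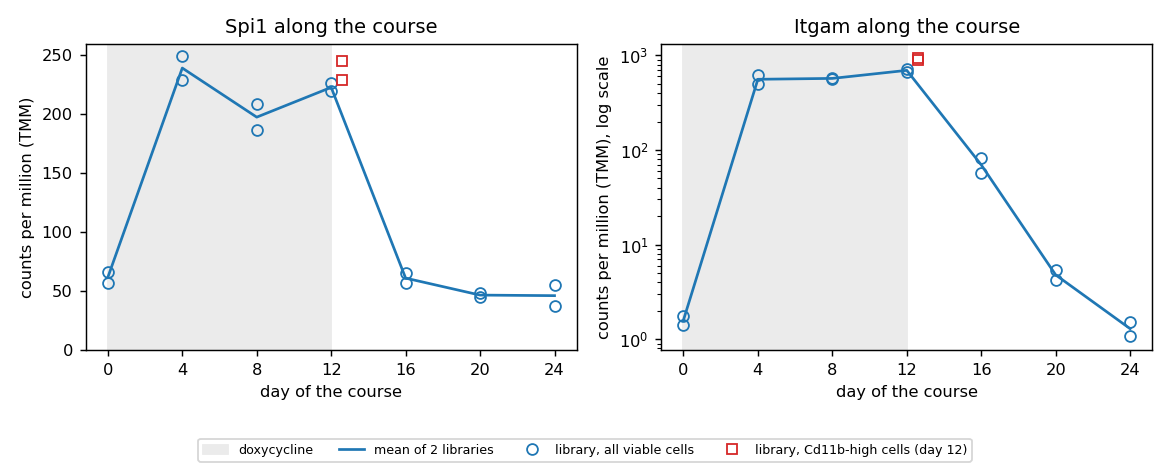
Normalised CPM of Spi1 (linear axis) and Itgam (log axis) against the day of the course, with 1 open circle per library of viable cells, a line through the mean of 2 libraries, the doxycycline phase shaded, and squares for the Cd11b-high libraries of day 12, drawn beside it. Spi1 rose from 61.5 CPM at day 0 to 239 CPM at day 4 and was back at 60.8 CPM 4 days after withdrawal, while Itgam went from 1.59 to 694 CPM at day 12 and back to 1.29 CPM.

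The day 12 against day 0 comparison asked what 12 days of doxycycline changed. Alox15, a lipoxygenase, had the largest rise of the genes that met the naming rule and went from 0.363 ± 0.409 to 314 ± 0.584 CPM (log2 fold 9.58, SE 0.41). Gapt, an adaptor protein, went from 0.427 to 254 CPM, Ptprc, which encodes the leukocyte antigen CD45, from 0.155 to 66.8 CPM, and Clec5a, a myeloid lectin receptor, from 0.155 to 52.1 CPM. Ngp, a neutrophil granule protein, had 1 read at day 0 and 707 at day 12, a ratio of 481 with a 95% counting interval from 86.1 to 19000. The largest falls were those of Il9r (log2 fold -6.91, SE 0.36; 95.3 to 0.784 CPM), which encodes the interleukin-9 receptor, Kis2 (-6.27), Ptpru (-5.83), a receptor phosphatase, Adamts3 (-5.69), Col5a3 (-5.68), a collagen chain, and Ptgds (-5.15), a prostaglandin D synthase. Each of these had an edgeR adjusted p of at most 3.2e-08.

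Genes of granulocytes and of myeloid signalling rose as groups at day 12. Of 23 textbook PU.1 target genes, 17 rose and 1 fell (camera adjusted p = 1.7e-19 and adjusted p = 0.00025 with an estimated correlation), among them Ncf1, a subunit of the phagocyte oxidase, from 24.1 to 423 CPM. Of 15 neutrophil secondary granule and maturation genes, 14 rose and 0 fell (camera adjusted p = 3.4e-13, and 0.017 as adjusted p with an estimated correlation). Lcn2 rose 62.6-fold, S100a9 54.0-fold and Padi4 6.43-fold. Of 10 eosinophil markers, 9 rose and 0 fell (camera adjusted p = 1.9e-13, and 0.017 as adjusted p with an estimated correlation), with Siglecf at 79.3 ± 1.53 CPM against 4.06 ± 0.516 and Ccr3 at 12.7 ± 1.63 against 0.357 ± 0.121. Of 19 Fc receptor and ITAM signalling genes, 16 rose and 1 fell (camera adjusted p = 2e-13, and 0.00042 as adjusted p with an estimated correlation), with Tyrobp up 40.6-fold and Sirpa 4.61-fold. All 8 measured complement and complement receptor genes rose (camera adjusted p = 3e-09, and 0.011 as adjusted p with an estimated correlation), including C3 (log2 fold 3.39, SE 0.27) and Itgb2 (2.44, SE 0.14).

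Several other groups moved up with a test that did not hold with an estimated correlation. Of 37 lysosomal genes, 26 rose and 2 fell (camera adjusted p = 2.4e-08; adjusted p = 0.14 with an estimated correlation), with Man2b1 at 1420 CPM against 226 and Psap at 1390 against 340. Of 26 interferon-stimulated genes, 16 rose and 3 fell (camera adjusted p = 0.0052; adjusted p = 0.077 with an estimated correlation), with Ddx58 up 3.28-fold. Of 12 cytokine and chemokine genes, 9 rose and 1 fell (camera adjusted p = 0.0018; adjusted p = 0.077 with an estimated correlation), with Il1rn, the interleukin-1 receptor antagonist, up 4.75-fold. Of 8 megakaryocyte and platelet markers, 5 rose and 0 fell (camera adjusted p = 0.017; adjusted p = 0.077 with an estimated correlation), with Itgb3 up 4.91-fold and Itga2b 3.01-fold. Of 16 macrophage and monocyte markers, 7 rose and 3 fell (camera adjusted p = 0.025; adjusted p = 0.19 with an estimated correlation; 0.072 without day 0 replicate A). Adgre1, the F4/80 antigen, rose 10.2-fold and Lyz2, lysozyme, 6.02-fold.

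Several azurophil granule genes, which mark immature granulocytes, and many genes of ribosome assembly went down at day 12. Of 9 azurophil granule genes, 3 rose and 5 fell (camera adjusted p = 0.0088; adjusted p = 0.19 with an estimated correlation). Mpo, myeloperoxidase, fell from 601 ± 21.9 to 30.3 ± 2.73 CPM (log2 fold -4.31, SE 0.20), Elane from 79.5 to 11.1 CPM and Ctsg from 223 to 35.2 CPM. Of 32 ribosome biogenesis genes, 18 fell and 3 rose (camera adjusted p = 0.00048; adjusted p = 0.31 with an estimated correlation), with Polr1b at log2 fold -1.71, Gnl3 at -1.47 and Nop56 at -1.31. Of the 13 lists that the camera test did not call, the 14 stem and progenitor genes gave 3 rises and 4 falls, with Cd34 up (log2 fold 2.32) and Muc13 down (log2 fold -4.53). The mitosis genes gave 13 rises and 2 falls of 30, the DNA replication genes 12 and 14 of 40, the cholesterol synthesis genes 11 and 4 of 23, and the p53 target genes 7 and 3 of 19. The haematopoietic transcription factors gave 11 rises and 7 falls of 29, with Irf5 up 14.1-fold and Gfi1 at log2 fold -1.13. The MHC class II genes gave 4 rises and 1 fall of 8, the immediate-early and heat-shock genes 5 and 5 of 16, the basophil and mast cell markers 3 and 4 of 9, and the dendritic cell markers 4 and 1 of 7. The erythroid markers gave 0 rises and 4 falls of 5 (camera adjusted p = 0.1, and 0.018 without day 0 replicate B), the B cell markers 0 and 1 of 5, and the T and NK cell markers 2 and 3 of 8.

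In the test of single genes, edgeR called 8654 of 13652 genes between day 12 and day 0, 4095 higher and 4559 lower at day 12, and 3756 of them differed by over 2-fold (1715 up, 2041 down). Counts of list members adjusted over the list alone were the same except for the lysosomal genes (28 up) and the B cell markers (0 down). The median, mean and camera direction differed in sign for the stem and progenitor, p53 target, immediate-early and basophil lists, none of them called. Mitochondrially encoded genes took 7.36% and 6.35% of the counts at day 0 and 2.02% and 2.12% at day 12. With RLE factors 4381 genes were higher and 4244 lower, and with DESeq2 4307 and 4077, so the larger side depended on the scaling. Scaling by library size alone shifted the median of all genes by -0.13 and gave 3453 higher and 5401 lower genes. With that scaling the mitosis genes gave 12 rises and 7 falls, the p53 target genes 6 and 6, and the medians of the stem and progenitor, transcription factor and basophil lists changed sign. Day of the course and doxycycline moved together, and untreated cells of later days are not analysed here.

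**Figure D2:**
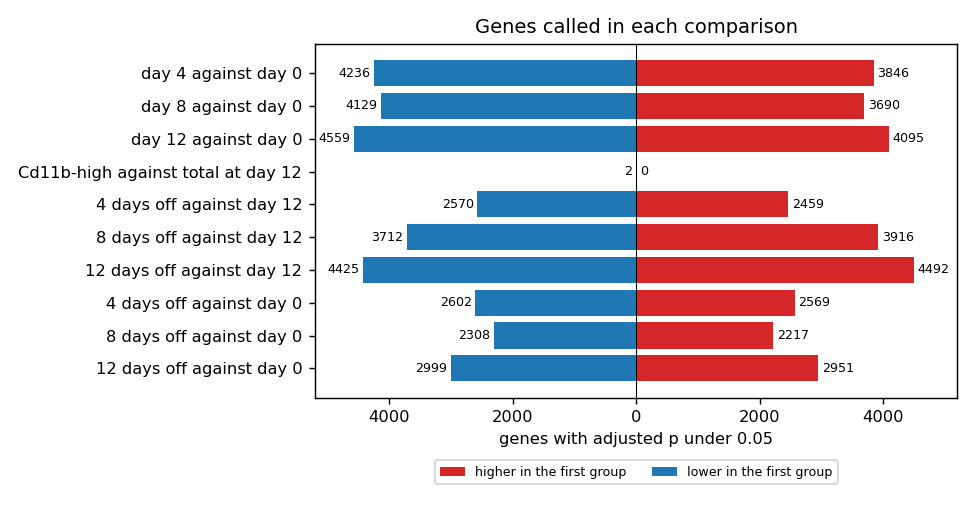
Number of genes with an edgeR adjusted p under 0.05 in each comparison, with genes higher in the first-named group to the right and genes lower to the left, both on 1 linear axis. The bars range from 2 genes between Cd11b-high and total cells of day 12 to 8917 genes (4492 higher, 4425 lower) between 12 days off and day 12.

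The earlier doxycycline times asked how soon the cells changed. Spi1 was 3.87-fold above day 0 at day 4 and 3.20-fold above it at day 8, with Itgam 354-fold and 362-fold above. At day 4, edgeR called 8082 genes (3846 higher, 4236 lower than at day 0) and at day 8 it called 7819 (3690 higher, 4129 lower). Along the first principal component, which held 62.5% of the variance, the 2 day 4 libraries stood at 44.8 and 51.8, those of day 8 at 43.2 and 46.0, those of day 12 at 53.9 and 51.3, and those of day 0 at -60.2 and -61.6.

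**Figure D3:**
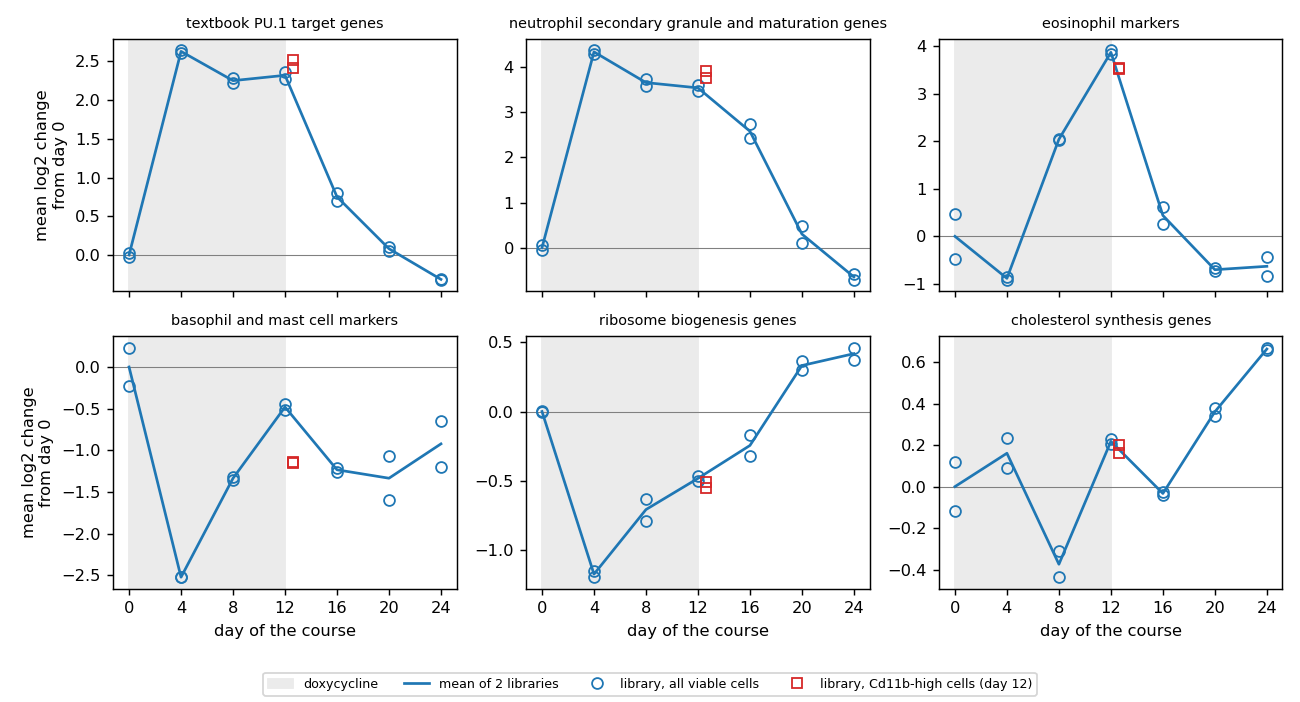
Mean log2 change from the day 0 mean over the members of 6 gene lists, per library (open circles) against the day of the course, with a line through the mean of 2 libraries, doxycycline shaded, and squares for the Cd11b-high libraries, drawn beside day 12. The PU.1 target and neutrophil lists stood above day 0 from day 4 to day 12, the eosinophil list stood below it at day 4 and highest at day 12, and the ribosome biogenesis list was lowest at day 4.

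The Cd11b-high against total comparison at day 12 asked how cells with high surface Cd11b differed from all viable cells of that day. Mcpt8, a basophil protease, was lower in the sorted cells, at 8.83 ± 0.142 CPM against 26.4 ± 0.556 (log2 fold -1.58, SE 0.14, edgeR adjusted p = 0.00018). Poln, named after its values were seen since it was the only other call, stood at 1.37 ± 0.364 CPM against 4.64 ± 0.171 (log2 fold -1.77, SE 0.26, edgeR adjusted p = 0.0445). Itgam stood at 912 ± 40.2 CPM in the sorted cells against 694 ± 35.3 and did not pass the test (log2 fold 0.39, SE 0.16, edgeR adjusted p = 1). Spi1 stood at 237 ± 11 against 222 ± 4.72 CPM.

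Small shifts ran along lineage lists in the Cd11b-high cells. Of 9 basophil and mast cell markers, 0 were called higher and 1 lower, Mcpt8, and 4 were lower when adjusted over the list alone (camera adjusted p = 3.3e-30; adjusted p = 0.014 with an estimated correlation). Cpa3 stood at 781 against 1180 CPM and Prss34 at 3.79 against 6.43. The 15 neutrophil genes leaned up with 0 called (camera adjusted p = 1.3e-09; adjusted p = 0.036 with an estimated correlation), with Lcn2 at 228 against 173 CPM and Ngp at 24.1 against 15.1. The 23 textbook PU.1 targets leaned up with 0 called (camera adjusted p = 2.1e-05; adjusted p = 0.014 with an estimated correlation), with Lyz2 at 474 against 337 CPM. That list holds Itgam, the gene of the sort marker, and its partner chain Itgb2. Without both genes, left out after the result was seen, the camera adjusted p was 0.00024, and the adjusted p was 0.036 with an estimated correlation. The 10 eosinophil markers leaned down with 0 called, and 1 lower when adjusted over the list alone (camera adjusted p = 1.6e-07; adjusted p = 0.16 with an estimated correlation), with Ear1 at 57.2 against 90.3 CPM, a gene that shares sequence with its paralogs, and Alox15 at 235 against 314.

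Further lists passed camera in the Cd11b-high cells without holding with an estimated correlation. These were the erythroid markers, down (camera adjusted p = 0.014; adjusted p = 0.26 with an estimated correlation; 0.18 without Cd11b-high replicate A), with Gata1 at 28.0 against 44.6 CPM, and the complement genes, up (camera adjusted p = 0.014; adjusted p = 0.21 with an estimated correlation; 0.071 without day 12 replicate B and 0.69 without Cd11b-high replicate B). The complement list holds Itgam and Itgb2 too, and its camera call was lost without Itgam (adjusted p = 0.095) and without both (0.16). The MHC class II genes leaned up (camera adjusted p = 0.048; adjusted p = 0.26 with an estimated correlation; 0.27 without day 12 replicate B and 0.33 without Cd11b-high replicate A). The immediate-early and heat-shock genes leaned up (camera adjusted p = 0.047; adjusted p = 0.51 with an estimated correlation; 0.39 without day 12 replicate B), and their direction turned without Cd11b-high replicate B (0.9), while without Cd11b-high replicate A their camera adjusted p was 3.6e-05. The mitosis genes passed without Cd11b-high replicate B (camera adjusted p = 0.0095), and the ribosome biogenesis genes passed without day 12 replicate A (0.042) or Cd11b-high replicate A (0.025). Camera called 8 lists in this comparison, against 6 with RLE factors and 7 with a replicate block. The fry test, which asks only whether a list leans 1 way, called 1 of the 25 lists.

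In the test of single genes, edgeR called 2 genes between Cd11b-high and total cells, 0 of them higher, and 309 genes had an unadjusted p under 0.05. DESeq2 called 11 genes, limma-voom 1, and a fit of the 4 libraries alone 313 (155 higher, 158 lower), while leaving out any 1 of the 4 libraries left 1. Total viable cells hold Cd11b-high cells too, so the comparison is of a part with its whole. The median, mean and camera direction differed in sign for the stem and progenitor, cytokine, transcription factor, T and NK and dendritic lists, none of them called.

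The 12 days off against day 12 comparison asked what changed after withdrawal. S100a9, a calprotectin subunit, had the largest fall of the genes that met the naming rule and went from 367 ± 0.0217 to 0.537 ± 0.273 CPM (log2 fold -9.38, SE 0.39), and S100a8, its partner, from 42.5 to 0.186 CPM. Clec5a fell from 52.1 to 0.0930 CPM, Cd300lf from 35.3 to 0.116, and Alox15 from 314 to 1.53. Ptgds rose from 6.90 ± 0.1 to 1940 ± 867 CPM (log2 fold 8.14, SE 0.37), and was at 2560 CPM in replicate A and 1330 in replicate B. Kis2 rose 71.3-fold, Il9r 34.5-fold, Mpzl2 28.7-fold, Ankrd37 28.4-fold and H2-Ab1, an MHC class II chain, 26.6-fold. Each of these had an edgeR adjusted p of at most 9.3e-07.

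The groups that had risen on doxycycline came down. Of 23 textbook PU.1 targets, 21 fell and 1 rose (camera adjusted p = 5.9e-24; adjusted p = 7.3e-05 with an estimated correlation), with Ptprc from 66.8 to 0.402 CPM and Ncf1 from 423 to 42.1. The neutrophil list gave 14 falls and 0 rises of 15 (camera adjusted p = 1.9e-16; adjusted p = 0.0067 with an estimated correlation), with Lcn2 from 173 to 1.84 CPM. The eosinophil list gave 9 falls and 0 rises of 10 (camera adjusted p = 1.4e-16; adjusted p = 0.015 with an estimated correlation), with Siglecf down (log2 fold -6.15) and Il5ra, the interleukin-5 receptor chain, from 40.5 to 1.86. The Fc receptor and ITAM list gave 16 falls and 1 rise of 19 (camera adjusted p = 2.5e-14; adjusted p = 0.00034 with an estimated correlation), and all 8 complement genes fell (camera adjusted p = 1.2e-10; adjusted p = 0.0028 with an estimated correlation). The macrophage list gave 11 falls and 1 rise of 16 (camera adjusted p = 3.5e-05; adjusted p = 0.023 with an estimated correlation), with Adgre1 from 42.7 to 0.752 CPM. The megakaryocyte list gave 7 falls and 1 rise of 8 (camera adjusted p = 0.0052; adjusted p = 0.048 with an estimated correlation), with Itga2b from 634 to 99.2 CPM.

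Other lists passed camera without holding with an estimated correlation. Of 32 ribosome biogenesis genes, 27 rose and 0 fell after withdrawal (camera adjusted p = 4.2e-10; adjusted p = 0.067 with an estimated correlation), with Gnl3 up 3.86-fold, Rcl1 3.49-fold and Polr1b 2.84-fold. Myc, a regulator of cell growth, rose 2.49-fold, from 183 to 455 CPM. Of 23 cholesterol synthesis genes, 13 rose and 3 fell (camera adjusted p = 0.017; adjusted p = 0.52 with an estimated correlation), with Hmgcs1 up 2.49-fold. The lysosomal list gave 26 falls and 5 rises of 37 (camera adjusted p = 8.6e-05; adjusted p = 0.32 with an estimated correlation), with Man2b1 down to 256 CPM. The interferon list gave 16 falls and 2 rises of 26 (camera adjusted p = 0.0038; adjusted p = 0.067 with an estimated correlation; 0.054 without replicate B of 12 days off), and the cytokine list 8 falls and 1 rise of 12 (camera adjusted p = 0.0022; adjusted p = 0.065 with an estimated correlation). Among lists that camera did not call, the azurophil granule genes gave 4 rises and 1 fall of 9, with Mpo back from 30.3 to 427 ± 57.8 CPM. The haematopoietic transcription factors gave 4 rises and 14 falls of 29 (camera adjusted p = 0.13, and 0.024 without replicate A of 12 days off), or 3 and 13 when adjusted over the list alone.

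In the test of single genes, edgeR called 8917 genes between 12 days off and day 12 (4492 higher, 4425 lower), 3924 of them by over 2-fold. A fit of the 4 libraries of 12 days off and day 12 alone called 6001 genes (3136 higher, 2865 lower). With library size alone the split was 5050 higher and 3777 lower, with the median of all genes shifted by 0.10. The median, mean and camera direction differed in sign for the azurophil, p53, immediate-early, B cell and T and NK lists, none of them called. At 4 days off, edgeR called 5029 genes against day 12 (2459 higher, 2570 lower), with 2522 without replicate A of that time, 2818 without day 12 replicate A and 3148 without day 12 replicate B. At 8 days off it called 7628 (3916 higher, 3712 lower). With library size alone, the median of all genes shifted by 0.12 at 4 days off (3480 higher, 1906 lower) and by 0.14 at 8 days off (4929 higher, 2916 lower).

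Genes that changed on doxycycline moved back after withdrawal. Of the 4095 genes higher at day 12 than at day 0, 3062 (74.8%) were lower at 12 days off than at day 12, against 1327 for independent lists. Of the 4559 genes lower at day 12, 3106 (68.1%) were higher at 12 days off than at day 12, against 1500 for independent lists, and 376 genes moved in the same direction at both steps. These counts rest on the 8917 calls of the withdrawal step, for which a fit of its 4 libraries alone called 6001. Across genes, which are not independent replicates, the log2 folds of the steps had Pearson r = -0.79. Sharing the day 12 libraries alone gave a mean of -0.47 (-0.50 to -0.45) in 20 simulations of unchanged groups. Those groups held noise only, so their r cannot be set directly against the observed one. The covariance of the log2 folds was -1.34, against a simulated mean of -0.031. Day 8 against day 0, which shares no library with the withdrawal step, gave 2847 and 2909 genes against 1196 and 1359 for independent lists, and r = -0.75 against simulated values from -0.03 to 0.01. The Cd11b-high comparison had r = 0.23 across genes with day 8 against day 0, against simulated values from -0.03 to 0.03, and its 2 called genes were both lower at day 8 too. The simulated genes varied independently of each other, so these simulated ranges may be too narrow for real noise. A minus B correlated by up to 0.26 between groups. Between day 0 or day 8 and either group of day 12 it correlated by -0.05 to -0.03. Whether r = 0.23 exceeds real noise was not tested.

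**Figure D4:**
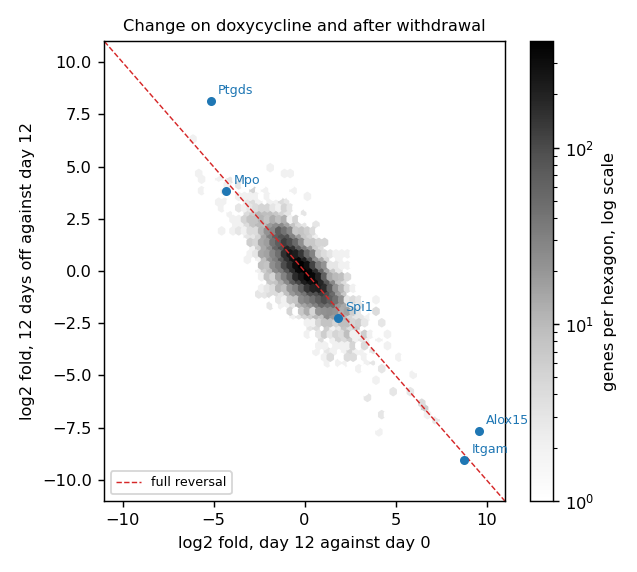
Log2 fold of each gene from day 0 to day 12 (horizontal) against its log2 fold from day 12 to 12 days after withdrawal (vertical), as hexagons shaded by the number of genes on a log scale, with 5 named genes as dots and a dashed line where a change would be fully undone. The cloud lies along the dashed line (Pearson r = -0.79 across genes), with Itgam and Alox15 at the lower right and Ptgds above the line.

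The 12 days off against day 0 comparison asked how far the cells ended from where they began. The largest rises over day 0 were those of Apln, the hormone apelin (2.40 ± 0.469 to 39.7 ± 5.52 CPM; log2 fold 4.07, SE 0.33), Ankrd37 (7.63 CPM at day 0, 134 and 65.4 CPM in replicates A and B of 12 days off), H2-Ab1 (6.60 to 83.7 ± 29.6 CPM), Spp1, osteopontin (60.9 to 738 ± 55.9 CPM), Eng, endoglin (11.6-fold), and Espn (10.2-fold). The largest falls were those of Ear1 (20.9 to 0.588 CPM, log2 fold -5.14, SE 0.31), an eosinophil ribonuclease gene with close paralogs, S100a8 (-4.84), ND4L (-3.67, SE 0.64), S100a9 (-3.63), Mcpt8 (-3.40) and Il5ra (14.8 to 1.86 CPM). ND4L is a mitochondrial gene that overlaps ND4, so its reads are uncertain. Each of these had an edgeR adjusted p of at most 0.00086.

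Metabolic and growth lists stood above day 0 at the end. Of 23 cholesterol synthesis genes, 17 were higher and 2 lower (camera adjusted p = 2.1e-07; adjusted p = 0.35 with an estimated correlation), with Hmgcs1 up 3.15-fold, Sqle 2.46-fold and Fdft1 2.35-fold. Of 32 ribosome biogenesis genes, 20 were higher and 0 lower, and 21 were higher when adjusted over the list alone (camera adjusted p = 0.00023; adjusted p = 0.54 with an estimated correlation), with Ncl at 1200 against 582 CPM. Of 8 MHC class II genes, 4 were higher and 0 lower (camera adjusted p = 0.0026; adjusted p = 0.33 with an estimated correlation), with H2-DMa up 3.34-fold and H2-DMb1 2.47-fold. The median of that list was 0.49 log2 units higher in replicate A than in replicate B of 12 days off, with H2-Ab1 at 105 and 62.8 CPM, and H2 genes can share reads. Cdkn1a, the p21 cell cycle inhibitor, was 3.20-fold higher.

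Some myeloid and replication lists stood below day 0. Of 16 macrophage and monocyte markers, 1 was higher and 10 lower (camera adjusted p = 0.0099; adjusted p = 0.33 with an estimated correlation; 0.054 without replicate B of 12 days off), with Clec7a at 38.8 against 116 CPM and Adgre1 at 0.752 against 4.20. Of 40 DNA replication genes, 3 were higher and 20 lower, and 21 were lower when adjusted over the list alone (camera adjusted p = 0.01; adjusted p = 0.54 with an estimated correlation; 0.17 without replicate B of 12 days off). Tk1 stood at 22.1 against 54.7 CPM and Tyms at 54.5 against 112. Of 9 basophil and mast cell markers, 2 were higher and 4 lower (camera adjusted p = 0.016; adjusted p = 0.54 with an estimated correlation; 0.27 without replicate B of 12 days off and 0.063 without day 0 replicate A), with Hdc at 71.4 against 239 CPM. Outside the lists that camera called, the textbook PU.1 targets gave 5 higher and 11 lower of 23 (camera adjusted p = 0.17), with Csf3r at 52.5 against 134 CPM, and the azurophil granule genes 2 higher and 5 lower of 9, with Ctsg at 52.5 against 223 CPM. Without day 0 replicate A, camera also called the neutrophil list (0.028), the azurophil list (0.0021) and the lysosomal list (0.023), and without day 0 replicate B the eosinophil list (0.0039). The mitosis genes gave 7 higher and 8 lower of 30, but 11 and 8 with RLE factors.

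In the test of single genes, edgeR called 5950 genes between 12 days off and day 0 (2951 higher, 2999 lower), 1757 of them by over 2-fold. The split depended on the scaling, with 3341 higher and 2693 lower with RLE factors and 3244 and 2578 with DESeq2. Library size alone gave 2760 higher and 3148 lower. Of the 1715 genes over 2-fold up at day 12, 1517 (88.5%) were called lower again at 12 days off, while against day 0 590 were still called higher, 205 were called lower and 920 (53.6%) were not called. Of the 2041 genes over 2-fold down, 1527 (74.8%) were called higher again, while against day 0 769 were still called lower, 238 were called higher and 1034 (50.7%) were not called. Over all 13652 genes, 43.6% were called against day 0, so the shares not called were no larger here than over all genes. These shares rest on the number of genes called against day 0, which was 7676 without replicate B of 12 days off. At 4 days off, edgeR called 5171 genes against day 0 (3031 without replicate B of that time). At 8 days off it called 4525 (2533 without replicate B and 2891 without replicate A of that time, 2709 without day 0 replicate A). The libraries of 12 days off stood apart from each other, with 874 genes over 2-fold apart and a Spearman correlation of 0.9785 across genes, against 153 to 392 genes and at least 0.9945 in the other groups. A fit of the 4 libraries of 12 days off and day 0 alone called 2160 genes. The median, mean and camera direction differed in sign for the stem and progenitor, interferon, erythroid and B cell lists, none of them called.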

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

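The tests of the opposite moves at day 4 and day 12 and of the rise of the eosinophil markers, and the tests of sequencing depth, of leftover cells and of the Cd11b-high comparison, were chosen after the result was seen. The tests of stages and of oxygen supply between replicates of 12 days off were written before theirs.

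Some named genes moved in opposite directions at day 4 and at day 12 of doxycycline. These 12 of 189 named genes were called in opposite directions against day 0 at the 2 times, as were 100 of all genes. Picking genes this way all but fixes that the difference passes its own edgeR test (adjusted p at most 3.3e-05), so that test adds no support. The difference of the log2 folds was 6.01 for Ear1, 10.37 for Ear2, 4.73 for Prss34, 3.28 for Cd200r3, 2.70 for Mcpt8, 2.25 for Itga2b, 1.73 for Csf1 and 0.91 for Cst7, which were below day 0 at day 4 and above it at day 12. It was -3.41 for Elane, -2.92 for Oas1a, -2.74 for Prtn3 and -1.50 for Cebpd, which went the other way. Ear2 had 0 reads at day 4 and 387 at day 12, so its rise was at least 140-fold against a floor of 3 reads, and its reads and those of Ear1 are uncertain because of paralogs.

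All 10 eosinophil markers rose between day 4 and day 12 (median log2 fold 5.21 over 10 members, the same with Ear2 at its bound), after 6 had been lower and 2 higher at day 4 than at day 0. The choice of scaling is argued against by a median of at least 5.08 over the TMM, RLE and library size scalings. The TMM factors at these times lay between 0.9379 and 1.052, so this test could hardly have come out otherwise. Reads shared between the Ear genes are argued against by the 7 of 7 members outside that family that rose, among them Prg2, a granule protein, from 29.4 ± 8.05 to 3220 ± 273 CPM (151 at day 0) and Epx, the eosinophil peroxidase, from 141 ± 33.3 to 4980 ± 390 (3430 at day 0). A rise of all granulocyte genes is argued against by the neutrophil list, whose median over the same days was -0.46, but 7 of 9 basophil and mast cell markers rose with a median of 2.15, so a rise shared with those cells is not excluded. No biological explanation was tested, and longer doxycycline, longer culture and a change in the mix of cells cannot be separated by the design.

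The 2 libraries of 12 days off differed more than those of any other group, with 874 genes over 2-fold apart. Sequencing depth is argued against, since the larger total was 1.05 times the smaller. Cells left from the doxycycline phase are argued against by the 3 textbook PU.1 targets that were abundant only then, whose median stood at 0.588% of the day 12 level in replicate A and 0.615% in replicate B (Tyrobp, the highest, at 6.04% and 5.52%). A different oxygen supply is argued against by the oxygen-sensitive genes, whose median A over B was 0.04 log2 units, at percentile 72.5 of 10000 random lists, although 1 member, Ankrd37, stood at 134 CPM in A against 65.4 in B. Different stages of the return may contribute and stay open, since r across genes of A over B with the change from 4 to 8 days off was 0.10, at the edge of what had been set to exclude it. That change is an earlier step than the one at which A and B differ. Along the first principal component, A stood at -87.3 and B at -68.0, with the libraries of 8 days off at -58.3 (A) and -51.5 (B). That order goes with different stages but was not set as a test.

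Cd11b-high cells and all viable cells of day 12 differed in 2 called genes. Dilution of the total by Cd11b-low cells may account for part of this and stays open: 38 genes were lower and 19 higher by over 0.5 log2 units in the sorted cells, a ratio of 2 at the edge of what had been set for it, and Itgam in the total stood at 76.2% of the sorted level (61.5% to 94.3%). The spread of the other groups may hide differences too, since a fit of the 4 libraries alone called 2.42% of the genes, 313 against 2. That share lay between limits set after the result was seen. Replicates of total and Cd11b-high cells had 153 and 208 genes over 2-fold apart, against up to 874 in other groups. The 2 calls are therefore no measure of the full difference, and how many of the 313 differ stays open. No biological explanation was tested for the differences that remain.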

How the results depend on the processing

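The filter at a mean of 1 CPM and the fit without mitochondrial genes were chosen after seeing the data. Of 130 alternative counts of called genes, 113 stayed within 1.5 times the main count, 10 of them from the fit without the planned filter. The planned filter removed 0 genes, so the fit without it tests nothing. For Cd11b-high against total (2 genes), library size alone gave 1, DESeq2 11, limma-voom 1, the 4 libraries alone 313, the filter at 1 CPM 1, and leaving out any 1 library 1. For 12 days off against day 0 (5950), the 4 libraries alone gave 2160. For 12 days off against day 12 (8917) the 4 libraries alone gave 6001, just within 1.5 times. Leaving out 1 library gave 2522 (without replicate A of 4 days off) to 4470 genes for 4 days off against day 12 (5029), 3031 (without replicate B of 4 days off) to 4238 for 4 days off against day 0 (5171), and 2533 (without replicate B of 8 days off) to 3385 for 8 days off against day 0 (4525). A library left alone in its group was assumed to vary like the other groups. The Spi1 log2 fold at 8 days off against day 0 (-0.41) passed with library size alone (-0.40), the 4 libraries (-0.39) and the replicate block (-0.40). The block was only an alternative, since A minus B correlated by over 0.1 between 8 of 28 pairs of groups. At 12 days off the Spi1 log2 fold (-0.42) missed the threshold with RLE factors, DESeq2, the filter at 1 CPM and without mitochondrial genes (-0.37 each) and with the 4 libraries (-0.41), and ran from -0.73 (without replicate A of 12 days off) to -0.09 (without replicate B). Lists called went from 12 to 5 with an estimated correlation and 19 with fry at day 12 against day 0. They went from 8 to 3 and 1 for Cd11b-high against total (5 without day 12 replicate B to 9 without day 12 replicate A), from 12 to 7 and 19 for 12 days off against day 12, and from 6 to 0 and 18 for 12 days off against day 0 (3 without replicate B of 12 days off to 8 without day 0 replicate A). The immediate-early list in Cd11b-high cells turned direction without Cd11b-high replicate B (adjusted p = 0.9), and had 3.6e-05 without Cd11b-high replicate A. The overlap of day 8 against day 0 with Cd11b-high (2 genes) was 1 with limma-voom and 1 to 3 without a library. Among named genes, 3979 alternative values kept direction and side of the threshold, 31 passed it newly, 24 lost it and 0 turned direction. Of the 3979, 313 came from the fit without the filter. Apart from Itgam, these genes were picked in the same data for large folds or low adjusted p, which favours stable values. The cause of the changes between settings was not tested. In the simulation of day 12 against day 0, 43.3% of genes changed 1.5-fold were found. That simulation gave 157 calls, against 8654 in the data, so its threshold on the unadjusted p was stricter. The share is therefore no measure of what the real comparison missed, but small differences can be missed.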

Other observations

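The oxygen-sensitive, mitochondrial and respiratory chain lists and the day 12 against day 4 comparison were all chosen after the result was seen, the first after Ankrd37 and Vegfa had stood among the named genes. List p-values were adjusted over these 3 lists alone within a comparison, but over 28 lists for day 12 against day 4. The lists fixed beforehand were adjusted over more lists, so an adjusted p over 3 lists cannot be set beside theirs. Whether the 3 lists would pass when adjusted together with those lists was not tested.

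Genes known to rise when oxygen is low were higher than at day 0 throughout the withdrawal phase. Of 22 such genes, 20 were higher than at day 0 at 4 days off, 20 at 8 days off (camera adjusted p = 5.9e-26; adjusted p = 0.0094 with an estimated correlation) and 19 at 12 days off (camera adjusted p = 5.1e-23; adjusted p = 0.011 with an estimated correlation), with 1 lower at each time. At 4 days off the list had an adjusted p of 0.051 with an estimated correlation (camera). At day 12 of doxycycline, 5 were higher and 6 lower than at day 0 (camera adjusted p = 0.85). Tested directly against day 12, 18, 19 and 19 were higher at 4, 8 and 12 days off, with camera adjusted p = 7.4e-12, 9.4e-10 and 1.7e-09, but the adjusted p was 0.13, 0.18 and 0.17 with an estimated correlation. Bnip3, a mitophagy receptor, stood at 103 ± 4.28 CPM at day 0, 58.7 ± 1.88 at day 12 and 545 ± 24.4 at 12 days off. Egln3, a prolyl hydroxylase that senses oxygen, went from 54.8 to 56.0 to 410 CPM at the same times, Slc2a1, a glucose transporter, from 82.5 to 96.4 to 310 CPM, and Ldha, lactate dehydrogenase, from 806 to 690 to 2660 CPM. Oxygen, culture density and PU.1 were not measured apart from each other, and no explanation was tested.

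Most mitochondrially encoded genes were lower than at day 0 at all later times. Against day 0, 12 of 13 were lower at day 4, 11 at day 12 and 12 at 12 days off (camera adjusted p = 4.5e-18; adjusted p = 0.011 with an estimated correlation), with 0 higher at each time. The adjusted p was 0.15 at day 4, 0.12 at day 8, 0.12 at day 12 and 0.051 at 4 days off with an estimated correlation (camera). From day 12 to 4 days off, 8 rose and 0 fell (median log2 fold 0.53, camera adjusted p = 0.013; adjusted p = 0.4 with an estimated correlation). Against day 12, 3 were higher and 0 lower at 8 days off (camera adjusted p = 0.68), and 3 higher and 4 lower at 12 days off (camera adjusted p = 0.56). CYTB, cytochrome b, stood at 9650 ± 1530 CPM at day 0, 3557 ± 111 at day 12 and 2090 ± 143 at 12 days off. Of 31 nuclear genes of the respiratory chain, 18 were lower and 1 higher at day 12 than at day 0 (camera adjusted p = 0.011; adjusted p = 0.74 with an estimated correlation). At 12 days off 5 were higher and 2 lower than at day 0 (camera adjusted p = 0.26).

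Between day 4 and day 12, edgeR called 3687 genes (2006 higher, 1681 lower at day 12). Of 9 basophil and mast cell markers, 7 rose and 0 fell (camera adjusted p = 2.6e-17; adjusted p = 0.047 with an estimated correlation), with Cpa3, a mast cell protease, from 277 ± 30.5 to 1180 ± 0.352 CPM, still below the 1830 CPM of day 0. All 9 had been lower at day 4 than at day 0. Of 32 ribosome biogenesis genes, 27 rose and 0 fell (camera adjusted p = 2.6e-17; adjusted p = 0.047 with an estimated correlation). Of 9 azurophil granule genes, 1 rose and 5 fell (camera adjusted p = 4.6e-07; adjusted p = 0.047 with an estimated correlation). Of 15 neutrophil genes, 3 rose and 8 fell (camera adjusted p = 0.00055; adjusted p = 0.17 with an estimated correlation). Camp, an antimicrobial peptide, fell from 46.4 ± 12.1 to 1.21 ± 0.0378 CPM and S100a8 from 813 ± 164 to 42.5 ± 6.85.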
